A study of Mus musculus with 8 samples.

How the data were processed

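Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was performed on the subpallium of wild-type CD-1 mouse embryos at embryonic day 12.5 (E12.5), pooled from several embryos per sample. The dissection took the septum together with the medial and lateral ganglionic eminences (MGE and LGE), the ventral forebrain swellings that give rise to basal ganglia neurons and cortical interneurons. Per the labels' protocols, chromatin was fixed with formaldehyde, sheared with a Bioruptor, precipitated with an antibody against the homeodomain transcription factor OTX2 or with goat IgG, and sequenced as single reads of 50 bp on a HiSeq. The 8 libraries were 3 OTX2 ChIP, 3 input chromatin (no antibody) and 2 IgG control libraries. The third experiment had no IgG library, per the labels' protocols. Groups and replicate numbers were taken from the sample titles.

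The deposited values were 1 peak list per library in BED form, so peaks were called by the authors per sample and not on pooled samples. Each line held a chromosome, a start, an end and a rank from 1 to the number of peaks in that list. The submitters' processing notes name BWA, MACS 1.4 and the genome build mm9, without roles or parameters. The control set against each library, the threshold, the quantity behind the rank and any filter are not given in the sources used here. The lists carried no height, fold enrichment, p-value or score, and no read totals, so the sequencing depth of each library is unknown. Ranks were therefore read only as an order within each list. Between lists these orders were compared by rank correlation and by the mean of rank percentiles. In the track names of the files both libraries of the third experiment were named differently from the other 6, with a tag that reads as a score and a further setting. Its meaning is not given in the sources used here, and peaks of the third experiment may have been called with other settings, so replicates 1 and 2 were treated as 1 processing batch and replicate 3 as another. Replicate 3 then stands alone in its batch, and values within replicates 1 and 2 are given beside the main pooled ones.

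All coordinates are those of the deposited files (mm9), written 1-based. The only gene table used here describes GRCm38. Over the 8 lists, 178 peaks on 6 of 20 chromosomes lay past the last gene of that table. Coordinates were not converted, so no peak was assigned to a gene. Distances to transcription start sites, sequence motifs and 16 gene lists fixed before the data were examined were not analysed here. From the GRCm38 table only the number of protein-coding genes per chromosome was used.

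Overlaps were computed in Python 3.11.15 with numpy 2.4.6 and scipy 1.17.1, and 4 of them were checked with bedtools 2.31.1 and gave identical counts. Peaks sharing at least 1 bp were called overlapping. An OTX2 region was a group of overlapping peaks with members from at least 2 of the 3 OTX2 lists and no overlap with any input or IgG peak. Chance overlap was measured with 1000 random placements of the peaks, each on its own chromosome between the lowest and highest position in any of the 8 lists, which stood for the length of the chromosome. With 1000 placements the smallest possible p is 0.001. The number of regions expected by chance came from 200 placements of all 3 lists (smallest p 0.005). Peak numbers were compared on a log10 scale with an exact two-sided permutation test of the library labels. Ranks of shared and unshared peaks were compared as percentiles of their own list with a two-sided permutation test (100000 resamples, smallest p 1e-05). This test had been planned on peak scores and was run on ranks because the lists hold no scores. Overlap with control peaks was compared between the best-ranked 25% of a list and the rest with Fisher's exact test. P-values were adjusted by the Benjamini-Hochberg method within each family (6 overlaps, 3 rank comparisons, 3 Fisher tests, 4 relations across autosomes). Peaks within a list are not biological replicates, so tests over peaks describe these libraries. The labels do not say whether the 3 experiments used separate litters. Percentages of peaks carry exact Clopper-Pearson 95% intervals, which cover counting error only.

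Regions named in the text were chosen by rules fixed before the data were examined: the 10 regions present in all 3 OTX2 lists with the best mean rank percentile, and the 5 bins of 1 Mb with the most regions, extended to ties. Alternatives were all 3 libraries or any 1 library, overlap of at least 50% of the shorter peak, the better-ranked 50% of each list, control peaks kept, each replicate left out, lists cut to 1298 peaks (the shortest) for the overlaps between replicates, control overlap within 1 kb, a circular shift as the random model, mean instead of median ranks, and a paired test by replicate number. Alternatives chosen after seeing the data were 200 bp windows at peak centres with lists of deposited or equal length, lists cut to 1298 peaks for the OTX2 regions, the named regions and bins and the rank agreement, control peaks kept for the rank agreement, moves of up to 500 kb as the random model, and every region setting applied to the X chromosome, spacing and autosome results.

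The code was tested on 20 simulated sets of 3 lists with the real peak numbers and widths and 200 planted common sites. All planted sites were recovered (100.0%), and between 200 and 201 regions were found in all 3 lists. Planted peaks shared their centres, so full recovery was fixed by construction and checks the code, not the sensitivity to real sites. For the rank test, 20 of 20 shifted sets simulated with the 1848 peaks of OTX2 replicate 1 gave p under 0.05, as did 3.75% of 400 unshifted sets.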

Results

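OTX2 binding was profiled by ChIP-seq in the E12.5 mouse subpallium, which comprised the septum and the medial and lateral ganglionic eminences. OTX2 is a homeodomain transcription factor of the forebrain and midbrain, and the study from which the lists come concerned its part in MGE patterning and septal identity. The data were peak lists of 3 OTX2 ChIP libraries, 3 input chromatin libraries and 2 IgG control libraries. The OTX2 lists held 1848, 1298 and 22325 peaks for replicates 1, 2 and 3. The input lists held 138, 142 and 235 peaks for replicates 1, 2 and 3, and the IgG lists held 149 and 182 peaks for replicates 1 and 2. Read depth was not recorded in the lists and is unknown.

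The first comparison asked how many sites were enriched with the OTX2 antibody over background measured in the same tissue. OTX2 libraries held more peaks than every input and IgG library. The log10 peak number was 3.58 ± 0.67 (SD, n = 3) in OTX2 libraries, 2.22 ± 0.13 (SD, n = 3) in input libraries and 2.22 ± 0.06 (SD, n = 2) in IgG libraries. The ratio of geometric means of OTX2 over input was 22.7 (exact two-sided permutation test, p = 0.10, the smallest p that 3 against 3 libraries allow). Without replicate 3 the ratio was 11.1. Both lists of the third experiment carry a tag in their track names that the other 6 lack, with the word score in it, and whether their peaks were called with the same settings is not given in the sources used here. By replicate number, OTX2 exceeded input 13.4-fold in replicate 1, 9.14-fold in replicate 2 and 95-fold in replicate 3, and it exceeded IgG 12.4-fold in replicate 1 and 7.13-fold in replicate 2.

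**Figure D1:**
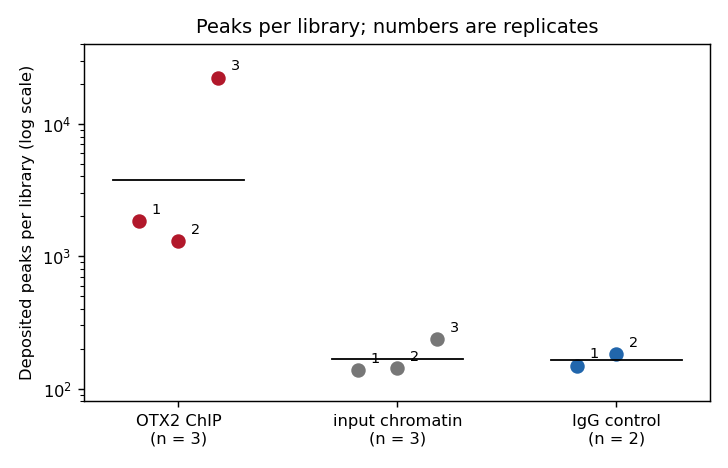
Number of deposited peaks per library on a log axis, by group; each point is 1 library, the digit beside it is its replicate number and the line is the geometric mean of the group. The OTX2 libraries lie between 1298 and 22325 peaks, above all input and IgG libraries, which lie between 138 and 235.

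The OTX2 peaks covered 0.491 Mb in replicate 1, 0.325 Mb in replicate 2 and 21.8 Mb in replicate 3. The median peak was 191 bp wide (interquartile range 151 to 284 bp) in replicate 1, 182 bp (152 to 276 bp) in replicate 2 and 827 bp (669 to 1080 bp) in replicate 3. The narrowest peak of replicate 3 was 303 bp. Median widths in the input lists were 152, 151 and 143 bp for replicates 1, 2 and 3. At the 789 regions found in all 3 OTX2 libraries, the best-ranked peak had a median width of 270 bp in replicate 1, 223 bp in replicate 2 and 1585 bp in replicate 3. In each OTX2 list the better-ranked peaks were the wider ones, with Spearman correlations across peaks between rank and width of -0.81, -0.75 and -0.73 for replicates 1, 2 and 3. Peaks of a list are not independent replicates.

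The next comparison asked whether the 3 experiments found the same sites. Most peaks of the shorter lists overlapped the long list of replicate 3. Replicate 3 overlapped 1625 of 1848 replicate 1 peaks (87.9%, 95% interval 86.4 to 89.4%) and 1195 of 1298 replicate 2 peaks (92.1%, 90.5 to 93.5%). Random placement gave 1.14% and 1.11%, respectively. Replicate 2 overlapped 794 replicate 1 peaks (43.0%, 40.7 to 45.3%, against 0.025% by chance), and replicate 1 overlapped 800 replicate 2 peaks (61.6%, 58.9 to 64.3%, against 0.040% by chance). Replicate 1 overlapped 7.19% of replicate 3 peaks and replicate 2 overlapped 5.25% of them, against 0.095% and 0.065% by chance. Each of the 6 overlaps exceeded all 1000 random placements (permutation test of peak positions, p = 0.001, the smallest they can give; Benjamini-Hochberg adjusted p = 0.001). With every peak reduced to 200 bp around its centre, replicate 3 overlapped 59.8% of replicate 1 and 60.9% of replicate 2 peaks. Requiring an overlap of at least 50% of the shorter peak left 87.9% and 92.0%. Centres of wide peaks may lie off the site, so the fall in 200 bp windows does not show how far the overlaps depended on width. Between lists of equal length (the best-ranked 1298 peaks), 57.4% of replicate 1 peaks lay in replicate 2, 68.3% of replicate 1 peaks lay in replicate 3, and 63.3% of replicate 2 peaks lay in replicate 3. With both length and width made equal (200 bp), the overlap of replicates 1 and 2 was the highest instead of the lowest of the 3, with 54.1% (51.3 to 56.8%) of replicate 1 peaks in replicate 2, 45.1% (42.4 to 47.9%) of replicate 1 peaks in replicate 3 and 41.3% (38.6 to 44.0%) of replicate 2 peaks in replicate 3.

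Overlap between replicates 1 and 2, and of replicate 3 peaks with either, fell along the authors' ranking. Of the best-ranked 10% of replicate 1 peaks, 93.5% (88.9 to 96.6%) were overlapped in replicate 2, and of the last 10%, 1.09% (0.132 to 3.87%). Of the best-ranked 10% of replicate 3 peaks, 64.5% (62.5 to 66.5%) were overlapped in replicate 1 or 2, falling to 13.8% (12.4 to 15.3%) in the next 10% and to 1 of 2232 peaks in the last. Overlap with replicate 3 showed no such steady fall: it stayed between 91.9% and 97.8% for replicate 1 peaks and between 94.6% and 98.5% for replicate 2 peaks in the first 8 of the 10% groups, and was 39.7% and 61.2% in the last. Peaks of replicates 1 and 2 that replicate 3 overlapped had median ranks of 994 and 738 among its 22325 peaks. The median rank percentile, where low values are better-ranked, was 45.6 for shared and 91.3 for unshared peaks of replicate 1, 47.7 and 92.8 for replicate 2, and 5.05 and 54.3 for replicate 3. Each of the 3 differences passed the permutation test (adjusted p = 1e-05, the smallest 100000 resamples can give). Better-ranked peaks were also wider and so more easily overlapped. The comparison was not repeated at equal width, so the part of width in these differences is unknown.

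**Figure D2:**
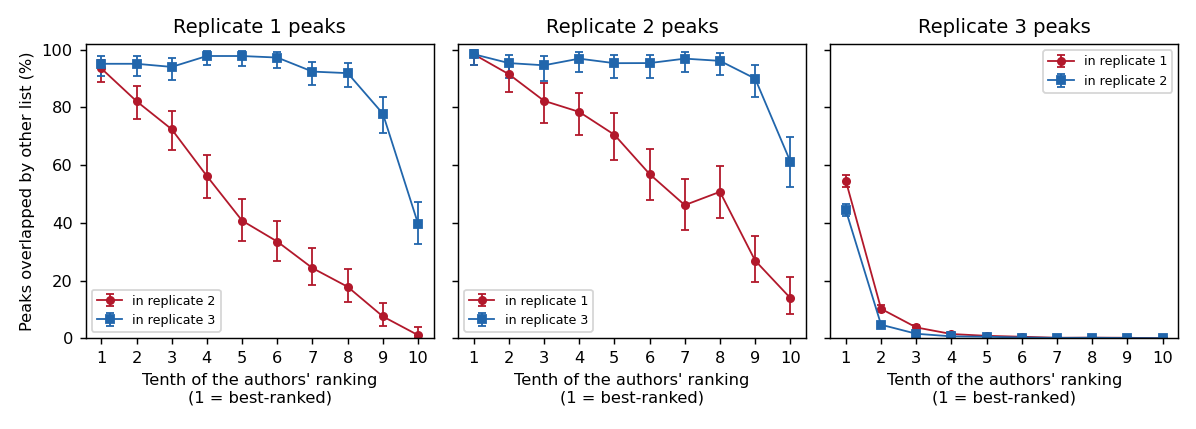
Percentage of peaks of each OTX2 replicate that were overlapped by each of the other OTX2 lists (vertical axis), by 10% groups of the authors' ranking (horizontal axis, 1 is best-ranked); bars are 95% Clopper-Pearson intervals. For replicate 1 peaks in replicate 2 the percentage goes from 93.5% in the first group to 1.09% in the last.

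Merging the 3 lists gave 1949 OTX2 regions that were present in at least 2 libraries and free of input and IgG peaks. Random placement of the lists gave 35.9 such regions on average and 57 at most in 200 placements (permutation test of peak positions, p = 0.005, the smallest they can give). All 3 libraries held 789 of the regions, replicates 1 and 3 alone 794, replicates 2 and 3 alone 361, and replicates 1 and 2 alone 5. Replicate 3 thus contributed to 99.7% of the regions, and the count depended on it. Without replicate 3, 759 regions were shared by replicates 1 and 2, and without replicate 1, 1150 were shared by replicates 2 and 3. The regions had a median width of 1372 bp (interquartile range 1081 to 1809 bp) and together covered 3.12 Mb. The width depended on the wide peaks of replicate 3, and without that library the regions had a median width of 333 bp. The 20381 replicate 3 peaks outside these regions (91.3% of its list) were seen in 1 library or overlapped a control peak. Where 2 libraries shared a region, their ranks correlated across regions with a Spearman rho of 0.66 for replicates 1 and 2 (794 regions), 0.77 for replicates 1 and 3 (1583 regions) and 0.78 for replicates 2 and 3 (1150 regions), each with a permutation p of 1e-04, the smallest 10000 permutations can give.

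The region with the best mean rank lay on chromosome 12 from 29501678 to 29503664 (mm9) and was ranked 2, 1 and 1 in replicates 1, 2 and 3. A region on chromosome 4 from 71827544 to 71830203 was ranked 1, 2 and 7, and 2 further OTX2 regions lay within 50 kb of it. A region on chromosome 8 from 100832615 to 100834407 was ranked 3, 3 and 6. A region on chromosome 19 from 15877453 to 15878665 was ranked 5, 6 and 2. On chromosome 15 a region from 85287739 to 85290080 was ranked 10, 5 and 15, with another region 5.55 kb away. On chromosome 1 a region from 191615220 to 191616348 was ranked 6, 10 and 5, and a second one from 41870215 to 41872566 was ranked 16, 9 and 14. On chromosome 16 a region from 72510439 to 72511794 was ranked 13, 7 and 3. On chromosome 5 a region from 99907540 to 99909754 was ranked 21, 4 and 9. On chromosome 3 a region from 88023161 to 88026808 was ranked 7, 14 and 8 and had 4 further regions within 50 kb. These 10 regions were free of control peaks, and none of the genes around them was identified because no mm9 annotation was used here.

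OTX2 regions lay close to one another more often than expected by chance. Of the 1949 regions, 484 (24.8%) had the centre of another within 50 kb, against 7.81% on average and 10.4% at most in 1000 random placements (permutation test of peak positions, p = 0.001, the smallest they can give). When each region was instead moved by up to 500 kb, chance was 15.1% on average and 18.4% at most, so the excess was 1.64-fold instead of 3.18-fold. These moves keep the density of regions along a chromosome only coarsely. They thin out dense 1 Mb stretches, so this chance value may be too low. Within replicates 1 and 2 alone the percentage was 17.1% against 3.20% for placement anywhere on the chromosome. Over the peaks of replicate 3 alone it was 72.0% against 59.6% (1.21-fold), and over regions of any 1 library 72.2% against 59.9% (1.21-fold). The densest 1 Mb bin lay on chromosome 18 from 55000001 to 56000000, with 12 regions, 9 of them in all 3 libraries. Bins on chromosome 3 from 34000001 held 10 regions, on chromosome 10 from 86000001 9 regions, and on chromosome 13 from 84000001 9 regions. The highest bin count in any random placement was 8, so 4 bins exceeded it. Another 5 bins held 8 regions each and equalled that count: chromosome 12 from 118000001, chromosome 2 from 146000001, chromosome 4 from 153000001, chromosome 5 from 112000001 and chromosome 8 from 12000001. Counts of most bins depended on single libraries, as did the total over the genome. That total fell from 1949 to 759 without replicate 3, 1150 without replicate 1 and 1583 without replicate 2. A fall in a bin is therefore not particular to that bin. Without replicate 3 the bin on chromosome 18 had 9 regions, chromosome 13 had 7 and chromosome 2 had 6, while chromosome 3 had 3, chromosome 10 had 4, chromosome 12 had 3, chromosome 8 had 5, and chromosomes 4 and 5 had 2 each. Without replicate 1 the bins on chromosomes 3, 12, 4 and 5 had 6, 5, 4 and 5 regions, and without replicate 2 the bin on chromosome 5 had 5. Of these 9 bins, those on chromosomes 18, 10, 13, 12 and 2 also held 1 or 2 control peaks.

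**Figure D3:**
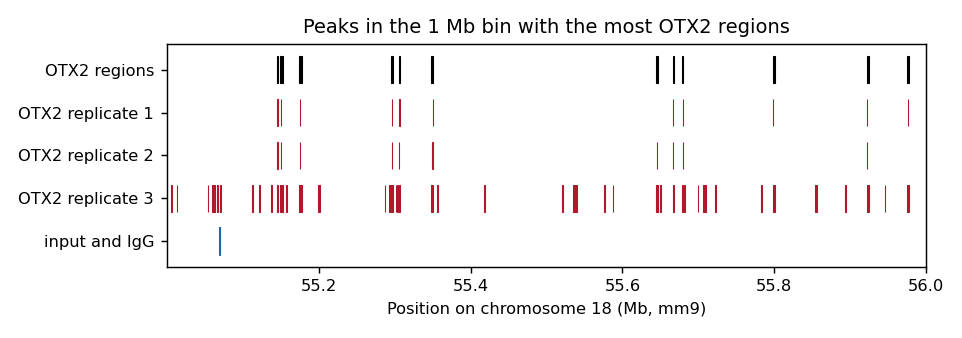
Map of the 1 Mb bin with the most OTX2 regions, on chromosome 18 (horizontal axis, position in Mb, mm9), to scale; rows show the OTX2 regions, the peaks of OTX2 replicates 1 to 3, and all input and IgG peaks. The bin holds 12 regions, 11, 10 and 42 peaks of replicates 1, 2 and 3, and 2 control peaks.

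The last comparison set the OTX2 lists against the background peaks. Input and IgG peaks overlapped 63 replicate 1 peaks (3.41%, 2.63 to 4.34%), 63 replicate 2 peaks (4.85%, 3.75 to 6.17%) and 46 replicate 3 peaks (0.206%, 0.151 to 0.275%). Random placement gave 0.071%, 0.015% and 0.032%, and all 3 overlaps exceeded it (permutation test, p = 0.001, the smallest 1000 placements can give). Replicate 1 has 1 peak on mitochondrial DNA, as does each control list, and placement kept it there. Its chance value is therefore not comparable with those of replicates 2 and 3, which have no such peak. In replicate 1 the overlapping peaks were concentrated at the top of the list, with 8.66% of the best-ranked 25% and 1.66% of the rest (Fisher's exact test, odds ratio 5.62, p = 5.35e-11, adjusted p = 1.6e-10). In replicate 2 the percentages were 4.63% and 4.93% (Fisher's exact test, odds ratio 0.936, p = 1.000, adjusted p = 1.000), and in replicate 3 0.323% and 0.167% (odds ratio 1.93, p = 0.039, adjusted p = 0.058). These Fisher tests count peaks as independent, although many shared a locus. The recurrent control clusters described below held 53 replicate 1 peaks, 30 of them in 1 cluster on chromosome 2. The small p-value of replicate 1 therefore counts many peaks from few loci. Removing regions with a control peak took 40 regions out of the OTX2 set.

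Background peaks recurred at a few places in every library. Of 638 merged control intervals, 574 appeared in 1 control list and 15 in all 5. Control peaks within 100 kb of one another formed 5 clusters with at least 3 peaks in each control list. The largest spanned 157.5 kb of chromosome 2 from 77707714 to 77865190 and held between 20 and 37 peaks in each of the 5 control lists, 30 and 29 peaks of OTX2 replicates 1 and 2 and 5 of replicate 3. The other clusters lay on chromosome 1 from 173448272 to 173509993, on chromosome 7 from 38960826 to 38986336, and on chromosome X from 123299937 to 123312933 and from 166408250 to 166442982. The 5 clusters held 32.6%, 37.3% and 20.9% of the peaks of input replicates 1, 2 and 3, 30.9% and 34.6% of those of IgG replicates 1 and 2, and 2.87%, 4.08% and 0.067% of those of OTX2 replicates 1, 2 and 3. All 5 had peaks in each of the 3 OTX2 lists, and no OTX2 region remained in them after regions with control peaks were removed. Peaks of OTX2 replicate 3 were wider, up to 46712 bp, and 1 wide peak can span several narrow ones. Its lower counts and percentage in the clusters therefore do not show less background there.

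Autosomes carried between 0.583 and 1.05 OTX2 regions per Mb, with a median of 0.827. Chromosomes 13, 19 and 9 had the highest densities, of 1.05, 1.03 and 1.01 per Mb, and chromosomes 15 and 6 the lowest, of 0.58 each. Chromosome X carried 25 regions, 0.155 per Mb, which was below all 19 autosomes. Its density was 0.194 times that of the autosomes together (95% interval from the exact binomial 0.125 to 0.287). With replicates 1 and 2 alone it was 0.099 (0.032 to 0.232, from 5 X regions). Over all deposited peaks the ratio was 0.255, 0.293 and 0.255 in OTX2 replicates 1, 2 and 3. In the input and IgG lists pooled the ratio was 1.13 (0.855 to 1.48), and outside the 5 recurrent clusters it was 0.209 (0.090 to 0.415). Across the 19 autosomes the number of regions correlated with chromosome extent (Pearson r = 0.81, permutation p = 3e-05, adjusted 6e-05; Spearman rho = 0.74, p = 5.1e-04, adjusted 6.8e-04; r = 0.73 without chromosomes 1 and 19, the farthest from the median). With replicates 1 and 2 alone r was 0.69. The number of regions also correlated with the number of protein-coding genes in GRCm38 (r = 0.49, p = 0.033, adjusted 0.033; rho = 0.51, p = 0.026, adjusted 0.026; r = 0.49 without chromosomes 7 and 2). The second relation missed the threshold with replicates 1 and 2 alone (r = 0.45, permutation p = 0.052). It was not adjusted for chromosome extent, with which the regions correlated more strongly (r = 0.81). A relation with genes apart from extent is therefore not shown. The relations with extent and with genes were 2 of 4 tested, the others being the same for replicate 3 peaks (r = 0.91 with extent and 0.68 with genes).

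**Figure D4:**
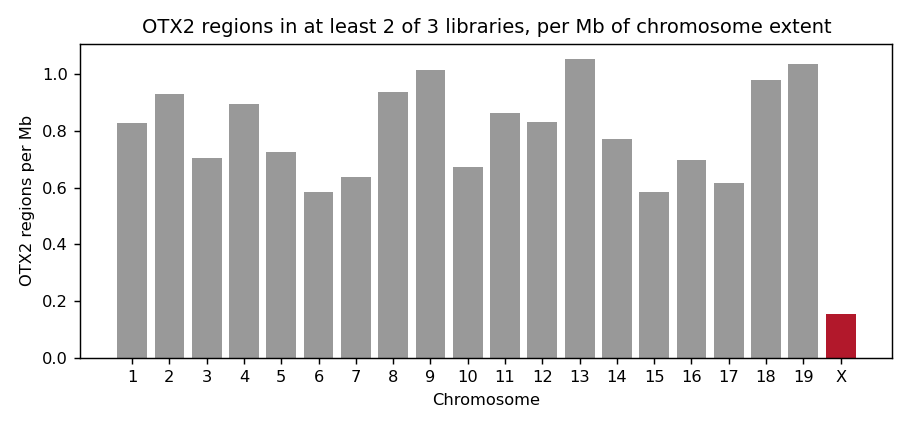
OTX2 regions per Mb of chromosome extent (vertical axis) for each autosome (grey bars) and chromosome X (red bar). Autosomes lie between 0.583 and 1.05 regions per Mb and X at 0.155.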

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

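No call in the 6 replicate overlaps, the 3 rank comparisons, the 3 control overlaps or the spacing of regions changed under any alternative run, and none of these reversed its direction against chance. Each of these tests gave the smallest p that its placements or resamples allow, in the main setting and in every alternative. The unchanged calls therefore say little about stability. The order of the overlaps among replicates did change: at equal length those with replicate 3 were above that of replicates 1 and 2, and in 200 bp windows of equal length below it. Of 311 alternatives, 263 stayed on the same side of their threshold or within the set limits, and 46 values without a test moved beyond them, 37 of these being region counts in single 1 Mb bins. Of those that stayed, 100 concerned the 10 named regions, which most settings could not remove. Peak-number tests by replicate block or without 1 replicate could not pass the threshold, so the tally overstates stability. The peak-number ratio was 22.7 (p = 0.036, exact permutation test, the smallest that 3 against 5 libraries allow) with input and IgG together as controls, which passes the threshold because more libraries enter. It was 11.1 to 35.7 without 1 replicate, where no p under 0.333 is possible. The number of OTX2 regions was 789 in all 3 libraries, 22534 in any 1 library, 989 in the better-ranked 50% of each list and 1117 with 1298 peaks per list, each by construction from fewer or more lists or peaks, and 759 to 1583 without 1 OTX2 replicate. The X to autosome density ratio was 0.095 in all 3 libraries, 0.121 with 1298 peaks per list, and 0.099 to 0.181 without 1 OTX2 replicate; the cause was not tested. The correlation of regions with protein-coding genes over autosomes was 0.447 to 0.482 without 1 replicate and lost its call without replicate 3 (p = 0.052), where fewer regions remain. The 10 named regions were chosen as the best-ranked ones present in all 3 lists, so most alternatives could not remove them and say nothing about their stability. The pairing by replicate number was not established: over 413 intervals with an input peak, the deviations of same-numbered OTX2 and input libraries correlated at 0.086, 0.054 and 0.074, although each OTX2 library correlated best with its own number. With the replicate block the peak-number ratio was 22.7 (exact sign-flip test, p = 0.25, the smallest that 3 pairs allow). A stricter score threshold pooled over libraries was not run, because the lists hold no scores. Tests of gene position, motifs and gene lists were not run without an mm9 genome and annotation. Depth is unknown, so a site missing from the shorter lists of replicates 1 and 2 cannot be called unbound.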

Other observations

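The tests on the X chromosome and on replicate 3 were chosen after the result was seen. Those on the spacing of regions were written down before their own result, although the 500 kb moves were chosen after the lists had been seen. All explanations below are hypotheses tested on the data in which the pattern was found.

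Among the best-ranked 10% of their lists, few peaks of replicates 1 and 2 were missing from replicate 3. Of the 185 best-ranked peaks of replicate 1, 9 were not overlapped in replicate 3, and all 9 lay in the recurrent control clusters. Of the 130 best-ranked peaks of replicate 2, 2 were not overlapped and 1 of them lay in a cluster. Over the whole lists most missing peaks lay elsewhere: 30 of 223 such peaks of replicate 1 and 25 of 103 of replicate 2 were in the clusters. Each input and IgG list had 1 peak on mitochondrial DNA, as did OTX2 replicate 1. Peaks on unplaced contigs made up 0.036 to 0.108% of OTX2 lists and 0.000 to 1.65% of control lists.

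OTX2 regions lay close together. Splitting of single wide sites into neighbouring peaks is argued against as the whole cause, because after merging regions within 5 kb 22.0% of 1909 intervals still had another within 50 kb, above the highest of 1000 random placements (10.4%). Moving each region by up to 500 kb gave a mean of 15.1% and a maximum of 18.4%, against 24.8% observed. Against these moves the excess was 1.64-fold instead of 3.18-fold. The moves keep coarse density but thin out dense stretches at the megabase scale. They therefore cannot decide whether uneven density at that scale alone gives the spacing, which stays open. Regions near another were slightly better ranked in replicate 3 (median percentile 4.15 against 5.27 for regions alone, a difference of 1.12, permutation p = 0.001). The quantity behind the rank is not given, so whether stronger sites lie in groups stays open. Accessible chromatin shared by neighbouring sites also stays open and was not tested.

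OTX2 regions were sparse on the X chromosome. A low number of genes for its length is argued against as the whole cause. X had 25.9 regions per 1000 protein-coding genes (upper 95% bound 38.1) and the lowest autosome 46.8. X had 966 such genes on 161 Mb and 0.155 regions per Mb. Chromosomes 12 and 18 had fewer for their extent, 679 on 118 Mb and 511 on 86.7 Mb. They carried 0.831 and 0.981 regions per Mb. The other autosomes had more genes for their extent than X. Peaks of input and IgG outside the recurrent clusters were as sparse on X, with a ratio to autosomes of 0.209 (0.090 to 0.415) beside 0.194 (0.125 to 0.287) for OTX2 regions. Only 8 such X peaks enter this ratio, and with the clusters kept the control ratio was 1.13. The lists hold no read totals. Fewer usable X reads in every library therefore stay open and cannot be told apart from an effect of the antibody. A lower X copy number in pools containing males stays open: the ratio of 0.194 lies below the halved copy number of males, but the lists do not show how peak number follows signal. No biological explanation was tested, since the design has no group that bears on it.

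Replicate 3 had 14.2 times the mean peak number of replicates 1 and 2, and peaks 4.43 times as wide. A partly different set of sites at the top of its list stays open: lists of equal length overlapped by 65.6% between replicate 3 and the others and by 57.6% between replicates 1 and 2, but in windows of equal width by 43.2% and 54.1%. Centres of wide peaks may lie off the site, so neither comparison decides. A wider peak extension common to both libraries of the third experiment is argued against, because its input list had 0.945 times the median width of the other inputs. The input widths do not bear on an extension particular to the OTX2 list of replicate 3, which was not tested. A looser threshold cannot be told apart from greater depth or better enrichment: input replicate 3 had 1.68 times as many peaks as the other inputs, but the lists carry neither p-values nor read totals, and the tag in the track names of both lists leaves other calling settings open.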
